A study of Mus musculus with 3 samples.

How the data were processed

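The 3 arrays, each in 2 colours, were on 1 slide scanned once, so no batch of slides or scans could be tested. Each compared 1 tumour in red with the pool in green, per the labels, from 250 ng of total RNA with an RNA integrity number above 7, and all arrays had the same dye orientation. The scanner files give intensity values, deposited as mean spot signals and median local backgrounds, made with Agilent Feature Extraction. Its version is 9.5.3 per the submitters' processing notes and 10.7.3.1 per the file headers, a difference that was left open. Probe coordinates are those of mm9, per the file headers. Feature Extraction's processed intensity signals are background-subtracted, detrended and dye-normalised, and its log10 ratio is that of red over green processed signal, per the file headers. The authors' deposited value table holds log2 ratios of tumour over pool. At 99.8 to 99.9% of its filled probes the value lay within 0.01 of the scanner log ratio put on the log2 scale, which settled scale and direction, with no further centring. Its medians were -0.15, -0.13 and -0.11 on replicates 1, 2 and 3. It is blank for 48.4%, 48.3% and 49.6% of 39429 probes, by a rule not given in the sources used here.

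Probes were named through their accession in a RefSeq gene table of assembly GRCm38, used for names only. This named 26055 of 39429 probes, and 13374 kept the name in the files. Signals were background-corrected with normexp at an offset of 50, fitted on all spots, and normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and the 157, 167 and 190 gene spots with outlier flags were then left out, and the spots of a probe were averaged. Probes well above background on all 3 arrays in red or on all 3 in green were kept, which left 24175 probes. A gene was represented by its brightest kept probe, giving 19433 genes. Of 3993 genes with several kept probes, 2 had probes called in opposite directions. Values are log2 ratios of tumour over pool, and the offset pulls the ratios of dim genes towards 0.

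The ratios were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over genes, and the prior had 2.45 degrees of freedom. A gene was called at an adjusted p under 0.05 with a fitted difference of at least 2-fold. The labels describe the tumours as separate biological samples. The pool is 1 sample, and its aliquots on the arrays do not show variation among normal mice. The median log2 ratio of all genes was 0.05. For a gene not well above background in 1 channel on every array, a bound is given as at least N-fold. It is the brighter channel's mean over the dimmer channel's mean of, per array, the higher of its own signal and the lowest signal well above background, after loess and Aquantile, and it is open to dye bias. Such bounds apply to 210 genes called higher and 30 called lower. Where a dim signal lies above that lowest signal, the bound is the fitted fold itself. This held for Cxcl5, Camp, Vnn1, Cldn2, Ms4a1, Dkk2, Egr2, Cst11 and Rnase1, while the bounds of Cckar and Pde11a were smaller. With members at their bounds, list medians differed for the squamous list (0.61), the intestinal list (0.40) and, by less than 0.01, the adipocyte list, and for no other. Medians at bounds could hardly move for this reason, so they are no check on dim members.

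The 32 gene lists were fixed before the data were examined, as were the comparison, its test and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists. With a correlation estimated from the 3 arrays no list passed after adjustment, and 4 passed at an unadjusted p under 0.05. The macrophage list's estimate of -0.026 was below the preset, yet its unadjusted camera p rose from 1.15e-09 to 0.0221. For the chief cell list the estimate was -0.059, and the unadjusted camera p rose from 6.76e-05 to 0.0541. Failing with an estimated correlation is therefore not by itself a sign that a list's genes vary together. By fry, which tests whether a list's genes move one way and does not compare them with other genes, 19 lists passed. Lists share some genes. The text names Cdh1, Trp53 and Atp4b and the 8 genes with the largest and the 8 with the smallest log2 ratio. These 16 had to be called, of 1 sign on all arrays and well above background in both channels on all arrays. It also names the 4 genes with the largest bound in each direction and, for each list, up to 3 called members with the largest absolute log2 ratio. Where no member was called, the brightest member is named. A gene that the rule selects is not reported here. Unnamed, clone-named and antigen receptor segment genes were left out of the parts of the rule that rank all genes. Differences between list medians have 95% intervals from 10000 bootstrap resamples of genes.

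The test was tried on simulated data for all 19433 genes, each with its own spread, with 200 genes changed. At 2-fold 0% of changed genes were called, at 4-fold 74% and at 8-fold 94%, with 0, 1 and 5 unchanged genes called. With 200 changed genes the adjusted threshold was stricter than in the data, where 9207 genes passed. These shares are therefore not the recovery in the data, least of all at 2-fold. In a further run the 9207 genes that had passed were given their fitted values, and all others 0. Of the 1118 genes at 4-fold or more 95.4% were called, and 0.601% of calls were unchanged genes. High recovery was built into that run, which held no spread among normal mucosae and no dye effect. Its share of unchanged genes is therefore not an error rate for these data. Of 20 lists of 20 genes shifted by 1 log2 unit 20 were called, also with an estimated correlation, and of 20 unshifted lists 0 were called at the preset correlation. Genes were drawn independently there, so this does not show how the estimated correlation acts on genes that vary together. Alternatives were Agilent's processed signals, no background subtraction, an offset of 0, median centring, Aquantile, the authors' value table, other filters on dim probes, the median of a gene's probes, every probe tested, a trended robust prior, TREAT, an adjusted p under 0.01, outlier spots kept and each replicate left out. Centring on the spike-ins and on the tested genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The number of arrays limits the precision.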

Results

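Gene expression was measured in 3 primary diffuse-type gastric cancers of 12-month-old mice carrying Atp4b-Cre+, Cdh1loxP/loxP and Trp53loxP/loxP. In these mice the Cre recombinase is driven by the promoter of Atp4b, the beta subunit of the gastric proton pump of parietal cells. It deletes loxP-flanked parts of Cdh1, which encodes the cell adhesion protein E-cadherin, and of Trp53, which encodes the tumour suppressor p53. Each tumour was hybridised in red (Cy5) to its own 2-colour Agilent array. The same pool of 5 normal gastric mucosae was hybridised in green (Cy3) on all 3 arrays. The pool came from 12-month-old mice of the same floxed genotype without Cre, and its stroma had been removed mechanically in 30 mM EDTA, a step the labels give for the mucosae and not for the tumours. Each array held 43020 gene spots. The share well above background was 54.2%, 53.8% and 52.5% in green and 64.0%, 66.8% and 65.1% in red on replicates 1, 2 and 3. No spot was saturated. Over the 15566 genes well above background in both channels, the median SD between arrays was 0.06 log2 units for the green signal of the pool, 0.24 for the red signal of the tumours and 0.21 for the log2 ratio. Log2 ratios of 2 tumours correlated across genes with a Pearson r of 0.868 to 0.886, and genes are not independent replicates. The ratios share the pool as denominator and the dye orientation, which by itself makes them correlate, so r does not measure how alike the tumours were.

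The comparison asked how tumours arising after the combined deletion of Cdh1 and Trp53 differed from normal gastric mucosa. Cdh1 was 18.9-fold lower in the tumours, with a log2 ratio of -4.24 ± 0.85 (SD, n = 3) and values of -4.62, -3.27 and -4.83 on the 3 arrays (adjusted p = 0.00186). Its probe lies on chromosome 8 at 109193812 to 109193871 of mm9. Trp53 had a log2 ratio of -0.21 ± 0.15 (SD, n = 3) at a probe on chromosome 11 from 69404204 to 69404263 and did not pass the test (adjusted p = 0.161). Its mean log2 signals of 6.41 in red and 6.62 in green were close to the lowest well above background (5.62 and 6.10), which limits the difference that this probe can show. The ratio was -0.72 with Agilent's processed signals and -0.91 with centring on the tested genes (adjusted p = 0.00588), and was not called under any alternative. The loxP-flanked exons are not given in the sources used here, so neither probe could be placed inside or outside the deleted part, and the exon or UTR at each probe was not assigned. Atp4b, whose promoter drives the recombinase, was 114-fold lower, at -6.83 ± 0.14 (SD, n = 3; adjusted p = 0.000235; chromosome 8, 13386212 to 13386271).

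Of 19433 genes tested, 3696 differed at least 2-fold at an adjusted p under 0.05, with 1814 higher and 1882 lower in the tumours. Each of these had the same sign on all 3 arrays, which the calling rule nearly forces with so few arrays. Without the fold criterion 9207 genes passed, 4764 higher and 4443 lower. At least 4-fold differences were called for 503 higher and 615 lower genes, and at least 16-fold differences for 40 higher and 86 lower genes. The pool is 1 control sample, so the test against a ratio of 0 leaves out the spread among normal mucosae, and with tumours always in red a dye effect stays in every ratio. The balance of higher and lower genes depended on scaling: 93.3% of called genes were higher with centring on the median of all gene spots and 78.4% with centring on spike-in controls, against 49.1% with loess. Sizes also depended on it: the medians of 25 of 32 gene lists moved by more than 1.5-fold with median centring, all upward, 25 with spike-in centring, and 14 with Agilent's processed signals. Of 104 named genes, 85, 43 and 30 moved by more than 1 log2 unit under these settings.

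Genes of the differentiated cells of the gastric gland fell in all 3 tumours. Of 16 measured parietal cell genes, 15 were called lower, also adjusted over the list alone, with a median log2 ratio of -3.91. They included Kcne2, a potassium channel subunit needed for acid secretion (-7.51 ± 0.35), Atp4b, and Atp4a, the catalytic subunit of the proton pump (-6.61 ± 0.36; SD, n = 3 throughout). Of 8 chief cell genes, 6 were called lower and 1 higher, likewise adjusted over the list alone, with a median of -3.73. The chitinase Chia1 (-8.16 ± 0.21), the intrinsic factor gene Cblif (-7.89 ± 0.30) and the pepsinogen gene Pgc (-4.92 ± 0.25) fell. The member called higher was the cathepsin gene Ctsh (1.97), named after its value was seen. Of 15 surface and neck mucous cell genes, 14 were called lower, also adjusted over the list alone, with a median of -3.49. Among them were Gkn2 (-5.85 ± 1.70, and -4.87 without replicate 3), the gel-forming mucin gene Muc5ac (-5.26 ± 0.35) and Psca (-5.21 ± 0.39). Of 12 gastric endocrine cell genes, 9 were called lower (10 adjusted over the list alone), with a median of -2.63, or -4.25 with Agilent's processed signals, led by the chromogranin gene Chga (-5.68 ± 0.17), the somatostatin gene Sst (-4.65 ± 0.12) and Chgb (-4.14 ± 1.03). The camera set test gave adjusted p-values of 1.33e-10, 0.000166, 4.33e-08 and 1.16e-06 for the parietal, chief, mucous and endocrine lists. For each of these lists the adjusted p = 0.289 with an estimated correlation.

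**Figure D1:**
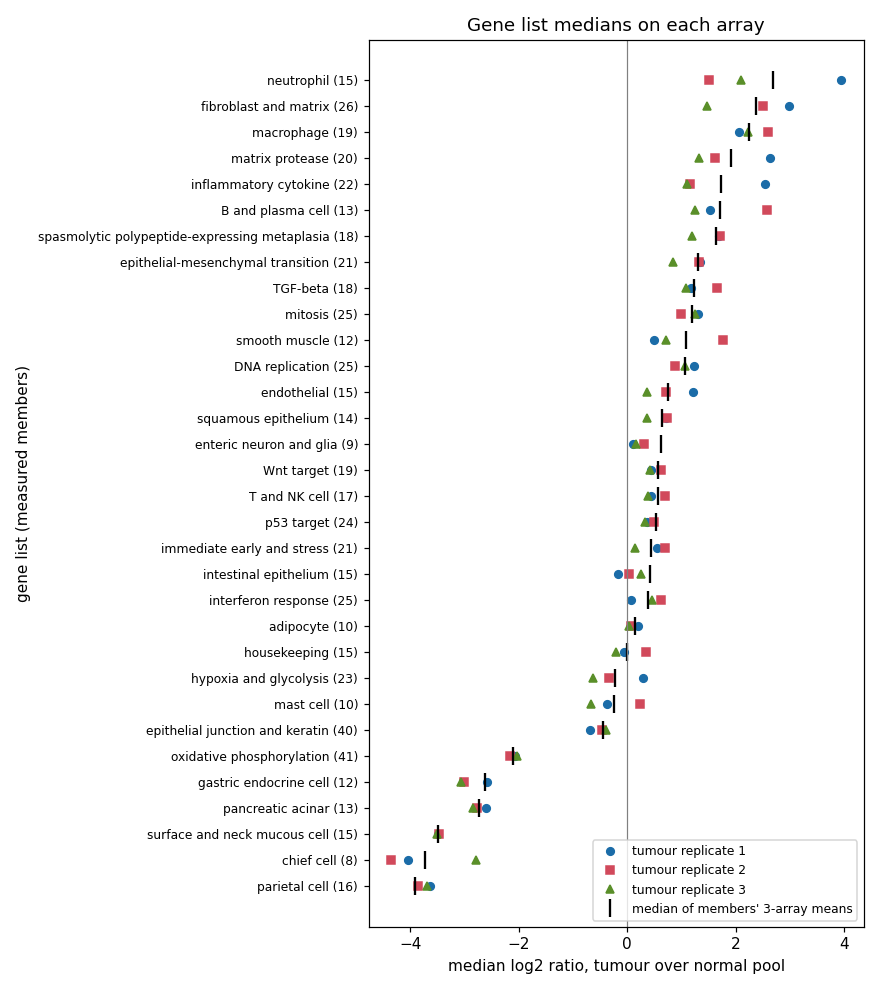
Median log2 ratio of tumour over normal pool (x axis) for each gene list (y axis, number of measured members in parentheses), with 1 symbol per tumour array and a black line for the median of the members' means over 3 arrays. By the black lines the parietal cell list lies lowest at -3.91 and the neutrophil list highest at 2.69, while the chief cell list lies lowest on replicates 1 and 2 and the macrophage list highest on replicates 2 and 3.

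Epithelial junction and keratin genes moved both ways. Of 40 measured, 5 were called higher and 12 lower, also adjusted over the list alone, with a median log2 ratio of -0.44. The claudin gene Cldn7 (3.94 ± 0.25) and the keratin gene Krt7 (3.93 ± 0.29) rose while Cdh1 fell. The list passed the set test (adjusted p = 0.0234), but adjusted p = 0.494 with an estimated correlation. Its median was -0.011 with centring on the tested genes, 0.08 with spike-in centring and 0.75 with median centring, and the test was not passed under any of these. Nor was it with Agilent's processed signals (adjusted p = 0.0554), the authors' values (adjusted p = 0.152), genes well above background in both channels (adjusted p = 0.0595), fry (adjusted p = 0.0831) or without replicate 1 (adjusted p = 0.0658). Genes of spasmolytic polypeptide-expressing metaplasia, a mucous cell state of injured gastric glands, had 10 members called higher and 2 lower among 18, with the same counts adjusted over the list alone. Their median was 1.63 (adjusted p = 0.0234, and adjusted p = 0.434 with an estimated correlation; 0.0528 with members of no other list only and 0.149 with median centring). The macrophage gene Cd14 (3.72 ± 0.25), the WAP-domain gene Wfdc2 (3.64 ± 0.15) and the hyaluronan receptor gene Cd44 (3.59 ± 0.49) led it, while Tff2 (-2.69) and Muc6 (-3.20), named after their values were seen, fell. Of 14 squamous epithelium genes 5 were called higher, also adjusted over the list alone, with a median of 0.63 (adjusted p = 0.0269, and adjusted p = 0.434 with an estimated correlation). They included Ivl, the involucrin gene (2.74 ± 0.75), Lor, the loricrin gene (2.26 ± 0.66), and Krt14 (1.89 ± 0.83), whose adjusted p was 0.0533 without replicate 2. The squamous list did not pass with the authors' values (adjusted p = 0.132) or without replicate 2 (adjusted p = 0.0522). Neither did it with median centring (adjusted p = 0.245), genes well above background in both channels (adjusted p = 0.140), centring on the tested genes (adjusted p = 0.0913) or fry (adjusted p = 0.0562), and its median was 1.53 with Agilent's processed signals. Of 15 intestinal genes, 4 were called higher and 3 lower (5 and 3 adjusted over the list alone; set test adjusted p = 0.679, and 0.0395 with spike-in centring). The antimicrobial lectin genes Reg3g (5.44 ± 0.72) and Reg3b (5.10 ± 1.11, and 5.69 without replicate 1) rose, and the fatty acid binding protein gene Fabp1 (-3.54 ± 0.32) fell. Reg3b was well above background in the pool on 1 array, and its ratio was 7.97 with Agilent's processed signals and 6.84 with an offset of 0. Of 13 pancreatic acinar genes 9 were called lower, also adjusted over the list alone, with a median of -2.73 (adjusted p = 3.61e-06, and adjusted p = 0.434 with an estimated correlation). The median was -5.92 with Agilent's processed signals, -6.95 with the authors' values, -5.40 with genes well above background in both channels, -4.32 with an offset of 0 and -1.27 with no filter on dim probes. The amylase gene Amy2a5 (-7.59 ± 0.21), the colipase gene Clps (-6.82 ± 0.24) and Pnliprp1 (-6.52 ± 0.23) fell furthest within it.

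Fibroblast and matrix genes rose in the tumours relative to the pool of stroma-depleted mucosae. Of 26 measured, 23 were called higher and 0 lower, also adjusted over the list alone, with a median log2 ratio of 2.38 (adjusted p = 1.17e-08, and adjusted p = 0.494 with an estimated correlation). Thrombospondin gene Thbs1 (3.91 ± 0.07), lumican gene Lum (3.62 ± 0.62) and fibulin gene Fbln2 (3.33 ± 0.43) rose most within it. Of 20 matrix protease and inhibitor genes, 13 were called higher (14 adjusted over the list alone), with a median of 1.91, or 3.06 with Agilent's processed signals (adjusted p = 2.66e-06, and adjusted p = 0.434 with an estimated correlation). Timp1, an inhibitor of metalloproteinases (4.25 ± 0.24), Mmp7 (3.99 ± 0.48) and Adam8 (3.68 ± 0.88) rose. Of 21 genes linked to epithelial-mesenchymal transition, 13 were called higher, also adjusted over the list alone, with a median of 1.30 (adjusted p = 2.08e-05, and adjusted p = 0.434 with an estimated correlation). They included the fibronectin gene Fn1 (4.57 ± 0.44), the moesin gene Msn (3.41 ± 0.48) and S100a4 (3.29 ± 0.71), genes that stromal and immune cells also express. Of 18 TGF-beta pathway genes 11 were called higher and 2 lower, also adjusted over the list alone, with a median of 1.23 (adjusted p = 0.000268, and adjusted p = 0.434 with an estimated correlation). Ccn2 (4.45 ± 0.52) and Ltbp2 (4.38 ± 0.09) rose, whereas Id1 (-2.03) and Id3 (-1.03), named after their values were seen, fell.

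Other stromal lists moved less. Of 12 smooth muscle genes 5 were called higher, with a median log2 ratio of 1.09 (adjusted p = 0.00560, and adjusted p = 0.494 with an estimated correlation). Cald1 (2.35 ± 0.28) and Tagln (1.72 ± 0.67) rose. Actg2 (1.70 ± 1.17) was called on all 3 arrays together, with values of 2.33 without replicate 1, 1.18 without replicate 2 (adjusted p = 0.108) and 1.59 without replicate 3 (adjusted p = 0.161). It lost its call with no filter on dim probes (adjusted p = 0.0714). Of 15 endothelial genes 4 were called higher, with a median of 0.75 (adjusted p = 0.00531, and adjusted p = 0.494 with an estimated correlation). The von Willebrand factor gene Vwf (2.79 ± 0.47) and Cldn5 (2.49 ± 0.99) rose, as did Sox17 (1.99 ± 1.19). Sox17 was 1.32 without replicate 1 and 2.22 without replicate 3 (adjusted p = 0.0897). It lost its call with the median of a gene's probes (adjusted p = 0.0503) and with no filter on dim probes (adjusted p = 0.0514). Counts adjusted over the list alone were the same for both lists. Neither list passed with median centring (adjusted p = 0.122 and 0.0938) or by fry (adjusted p = 0.0886 for both). Of 9 enteric neuron and glia genes 0 were called, with a median of 0.62 (set test adjusted p = 0.232). The list passed with no filter on dim probes (adjusted p = 0.0372) and by fry (adjusted p = 0.0474). Its brightest member, Snap25, had 0.62 ± 0.24, and was called at 1.83, 1.07 and 1.24 with median, tested-gene and spike-in centring. Of 10 adipocyte genes 1 was called higher and 1 lower (set test adjusted p = 0.698), Cfd at 2.42 ± 0.30 and Cidec at -1.59 ± 0.90. Cidec had an adjusted p of 0.0872 without replicate 2. It was not called at -0.51 with median centring or at -0.96 with the median of a gene's probes.

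Genes of myeloid and B cells rose in the tumours relative to the pool of stroma-depleted mucosae. Immune cells may have been removed from the pool with its stroma. The design cannot tell such removal apart from a rise in the tumours, for these lists or for the cytokine list below. Of 19 macrophage genes 14 were called higher, also adjusted over the list alone, with a median log2 ratio of 2.24 (adjusted p = 9.23e-09, and adjusted p = 0.289 with an estimated correlation). Cd14, the lipid receptor gene Trem2 (3.11 ± 0.26) and the Fc receptor chain gene Fcer1g (3.04 ± 0.17) led it. Of 15 neutrophil genes 11 were called higher (12 adjusted over the list alone), with a median of 2.69, or 1.91 without replicate 1 and 4.70 with Agilent's processed signals (adjusted p = 3.17e-05, and adjusted p = 0.494 with an estimated correlation). The calgranulin genes S100a9 (6.70 ± 1.06, and 6.12 without replicate 1) and S100a8 (6.55 ± 1.44, with 5.74 without replicate 1 and 7.14 without replicate 2) rose. So did the lactoferrin gene Ltf (4.68 ± 1.24, and 4.01 without replicate 1). Of 13 B and plasma cell genes 10 were called higher, also adjusted over the list alone, with a median of 1.71, or 4.06 with Agilent's processed signals (adjusted p = 0.00142, and adjusted p = 0.494 with an estimated correlation). The antigen receptor gene Cd79b (3.55 ± 1.01) and the coactivator gene Pou2af1 (2.98 ± 0.73) rose. Ms4a1 was at least 6.88-fold higher as a mean over the 3 arrays, at 2.78 ± 0.89. Its values were 2.47, 3.79 and 2.09 on replicates 1, 2 and 3. Of 17 T and NK cell genes 4 were called higher (5 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.0110, and adjusted p = 0.434 with an estimated correlation). The median was 2.08 with Agilent's processed signals and 1.43 with an offset of 0. It was 0.17 with genes well above background in both channels (adjusted p = 0.247), 0.30 with the authors' values (adjusted p = 0.160) and 0.36 with centring on the tested genes (adjusted p = 0.298), and the list did not pass under these 3 or with median centring (adjusted p = 0.204). The called members included the kinase genes Lck (1.90 ± 0.47) and Zap70 (1.27 ± 0.09) and the adhesion gene Cd2 (1.32 ± 0.55). With the median of a gene's probes Zap70 (0.89) and Cd2 (0.90) were not called. Of 10 mast cell genes 0 were called (adjusted p = 0.567), and Kit had -0.83 ± 0.77, or -1.24 without replicate 1, where it passed.

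Of 22 inflammatory cytokine genes measured, 11 were called higher, also adjusted over the list alone, with a median log2 ratio of 1.73, or 1.08 without replicate 1 and 3.63 with Agilent's processed signals (adjusted p = 0.000696, and adjusted p = 0.494 with an estimated correlation). The neutrophil attractant gene Cxcl5 was at least 46.9-fold higher as a mean over the 3 arrays, with a log2 ratio of 5.55 ± 1.91. Its values were 7.75, 4.38 and 4.52 on replicates 1, 2 and 3, with means of 4.45 without replicate 1 and 6.14 without replicate 2. The interleukin gene Il1b (3.29 ± 1.75) was 2.31 without replicate 1, 3.60 without replicate 2 (adjusted p = 0.0546) and 3.97 without replicate 3, and Ccl8 had 3.22 ± 0.52. The cytokine and the B cell list did not pass with median centring (adjusted p = 0.122 for both) or by fry (adjusted p = 0.0510 and 0.0615). Of 25 interferon response genes 3 were called higher and 1 lower, also adjusted over the list alone, with a median of 0.39 (adjusted p = 0.0160, and adjusted p = 0.494 with an estimated correlation; 0.123 without replicate 2 and 0.0554 with Agilent's processed signals). It did not pass with median centring (median 1.17), spike-in centring (median 1.12, adjusted p = 0.326) or fry (adjusted p = 0.0886). The immunoproteasome gene Psmb8 (1.83 ± 0.36) and the transcription factor gene Irf1 (1.34 ± 0.46) rose and Oasl1 (-1.47 ± 0.66) fell, though Oasl1 was at -0.08 with median centring, and was not called with that, tested-gene or spike-in centring.

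Cell cycle genes rose and respiratory chain genes fell. Of 25 mitosis genes 18 were called higher, with a median log2 ratio of 1.20 (adjusted p = 5.24e-09, and adjusted p = 0.434 with an estimated correlation), including Cenpe (1.67 ± 0.42), Plk1 (1.66 ± 0.15) and Aurka (1.53 ± 0.26). Of 25 DNA replication genes 13 were called higher, with a median of 1.06 (adjusted p = 5.28e-08, and adjusted p = 0.308 with an estimated correlation), including the helicase genes Mcm4 (1.90 ± 0.23) and Mcm5 (1.68 ± 0.30) and the ribonucleotide reductase gene Rrm2 (1.67 ± 0.23). All 41 measured oxidative phosphorylation genes were called lower, with a median of -2.11 (adjusted p = 5.11e-21, and adjusted p = 0.289 with an estimated correlation). Ndufb9 (-2.90 ± 0.13), Uqcrb (-2.87 ± 0.28) and Cox7a2 (-2.68 ± 0.13, and not called with median centring) fell furthest within the list. The list median was -1.31 with centring on the tested genes, -1.52 with spike-in centring and -0.55 with median centring. The mitosis and DNA replication medians were 2.29 and 2.14 with median centring and 1.53 and 1.38 with centring on the tested genes. Counts adjusted over the list alone were the same for these 3 lists. Parietal cells are rich in mitochondria, and their genes fell alongside.

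Among 24 p53 target genes 2 were called higher and 3 lower, also adjusted over the list alone (median 0.54; set test adjusted p = 0.178, and 0.0474 by fry). The cell cycle inhibitor gene Cdkn1a fell (-2.11 ± 0.98, and not called at -0.91 with median centring or at -0.99 with the median of a gene's probes), and Phlda3 (2.36 ± 0.30) and Tnfrsf10b (1.30 ± 0.20) rose. Of 19 Wnt target genes 4 were called higher (5 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.0185, and adjusted p = 0.434 with an estimated correlation; 0.0793 with the authors' values, 0.161 with median centring, 0.0913 with centring on the tested genes and 0.0540 with genes well above background in both channels). They were led by Cd44 and Sox4 (1.81 ± 0.08). Dkk2, a Wnt modulator gene, was at least 3.49-fold higher as a mean over the 3 arrays (1.80 ± 0.30). Of 23 hypoxia and glycolysis genes 4 were called higher and 5 lower (4 and 6 adjusted over the list alone; adjusted p = 0.405). The lactate transporter gene Slc16a3 rose (2.69 ± 1.21, and 2.03 without replicate 1), the carbonic anhydrase gene Car9 fell (-2.68 ± 0.94), and Hk2 (1.49 ± 0.87) lost its call without replicate 1 (1.00) and without replicate 3 (adjusted p = 0.0920). Of 21 immediate early and stress genes 6 were called higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0736). Klf4 was at -2.85 ± 0.32, Ier3 at 1.63 ± 0.67 and Egr2 at least 3.38-fold higher as a mean (1.76 ± 0.09). This list passed without replicate 3 (adjusted p = 0.0111), with centring on the tested genes (adjusted p = 0.0160) and with no filter on dim probes (adjusted p = 0.0268). Of 15 housekeeping genes 1 was called higher and 1 lower, also adjusted over the list alone (median 0.01; adjusted p = 0.845). These were Gusb (1.64 ± 0.36) and Sdha (-1.80 ± 0.14), a respiratory chain gene that was at -0.46 with median centring and not called.

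**Figure D2:**
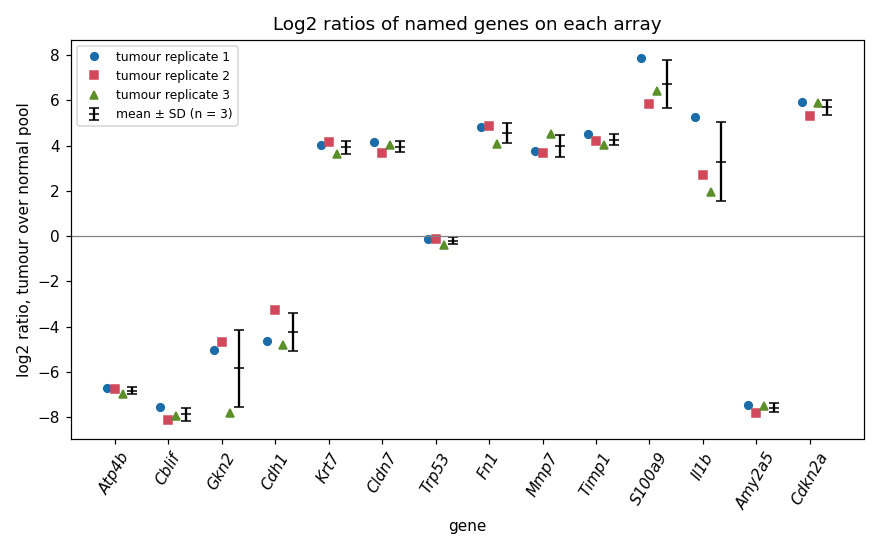
Log2 ratio of tumour over normal pool (y axis) for 14 named genes (x axis), with 1 symbol per tumour array and the mean with its SD over 3 arrays in black. The 3 Cdh1 values lie between -4.83 and -3.27, and Trp53 has a mean of -0.21.

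Among genes well above background in both channels on all arrays, the largest increases were those of S100a9, the mesothelin gene Msln (6.66 ± 0.35), S100a8, Reg1 (5.79 ± 0.56), Cdkn2a (5.69 ± 0.34), the surfactant protein gene Sftpd (5.65 ± 0.58), Reg3g and Ctla2a (4.93 ± 0.72). Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf, was 51.7-fold higher (adjusted p = 0.00036). Its log2 ratio was 6.91 with Agilent's processed signals, 7.47 with spike-in centring and 3.84 with the median of a gene's probes. The largest decreases were those of Chia1, Cblif, Amy2a5, Kcne2, the trypsin genes Try4 (-7.17 ± 0.35) and Try5 (-6.98 ± 0.34), the disulfide isomerase gene Pdia2 (-6.93 ± 0.15) and Atp4b. The Try, Reg and amylase genes have near-identical family members, so their probes may also detect these. Sox17 was well above background in the pool on 1 array and Ivl, Krt14 and Il1b on 2, and Fabp1 in the tumours on 2. Their log2 ratios were 3.89, 4.17, 3.35, 5.28 and -6.43 with Agilent's processed signals. Some genes were not well above background in the pool on any array. Among those, by means over the 3 arrays, Camp was at least 20.2-fold higher, at 4.34 ± 1.07 (3.73 without replicate 1). Vnn1 was at least 14.3-fold and the claudin gene Cldn2 at least 11.2-fold higher, at 3.84 ± 0.60 and 3.49 ± 0.66. Other genes were not well above background in any tumour. Among those, by means over the 3 arrays, the cholecystokinin receptor gene Cckar was at least 22.4-fold lower. Cst11 was at least 7.53-fold, Rnase1 at least 6.65-fold and Pde11a at least 6.51-fold lower.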

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

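Centring on the spike-ins and on the tested genes was chosen after seeing the data. With each replicate left out, 3438 to 3607 genes were called, 1661 to 1686 higher and 1777 to 1921 lower, and 22 to 25 lists passed. Against 3696 genes called (1814 higher, 1882 lower), Agilent's processed signals gave 6817 (3738 and 3079), an offset of 0 gave 5743 (3192 higher), median centring gave 8303 (7747 and 556), TREAT gave 1366 (509 and 857), and spike-in centring gave 8563 (6716 higher). Centring on the tested genes gave 3087 higher genes. TREAT asks for more than 2-fold by its construction, and the cause was otherwise not tested. The median log2 ratio of all genes moved by 0.72 with median centring and 0.56 with spike-in centring, and 364 of the 3696 genes changed sign with median centring. With the authors' values the median moved by -0.14, but over 15602 genes in place of 19433. Agilent's processed signals moved it by -0.007 over 19433 genes. The share called higher was 49.1%, and 93.3%, 78.4% and 59.2% with median, spike-in and tested-gene centring. Of 24 lists that passed, 14 did so under each alternative except the estimated correlation, with which 0 passed (4 at an unadjusted p under 0.05), and 14 lists passed with median centring. The epithelial junction and keratin list had a median of -0.011 with centring on the tested genes, where camera turned its direction without passing (adjusted p = 0.890), and of 0.75 and 0.08 with median and spike-in centring; the cause was not tested. Of 1631 values of 104 named genes under alternatives, 22 lost and 4 gained the call and 0 reversed. Aquantile changed no ratio, and no spot was saturated, so leaving out saturated probes was not run. No paired analysis was possible because there is 1 group of tumours against 1 pool, which also leaves no other split of the samples to count. Probes dim in the pool limit the ratios of genes low in normal mucosa.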

Other observations

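The genes and families named up to the spike-in controls, and the test of acinar genes by their green signal below, were chosen after their values were seen. The complement genes C3 (4.78 ± 0.37 log2 units, SD, n = 3) and C4b (3.13 ± 0.23) and the protease inhibitor gene Slpi (4.24 ± 0.33) were called higher in the tumours, and each was above 0 under the 6 scalings tried. These scalings are not independent checks. The authors' values of these genes equal Agilent's processed ratios, and spike-in centring shifts those ratios by a constant per array. The fetal transcripts H19 (3.39 ± 0.69) and Afp (3.07 ± 1.00) were called higher, while Igf2, another fetal transcript, was not called (0.16 ± 0.15, adjusted p = 0.260). Igf2 was well above background in the pool on 0 arrays and had a mean log2 red signal of 6.34, which limits its ratio. That ratio was 1.11 with Agilent's processed signals. Next to Cdkn2a in the genome, Cdkn2b had -1.09 ± 0.37, though it was at 0.19 with median centring. The quinone reductase gene Nqo1 (-4.22 ± 0.61) and the retinal dehydrogenase gene Aldh1a1 (-4.72 ± 0.55) were called lower. A related dehydrogenase gene, Aldh1a3, was called higher (3.81 ± 1.86, with 2.74 without replicate 2 and an adjusted p of 0.0544 without replicate 3).

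Of 376 symbol families with at least 6 measured genes, 36 passed camera and 0 with an estimated correlation (adjusted p = 0.920 with an estimated correlation for each family named here). All 7 Gstm glutathione transferase genes were called lower (median -1.59, adjusted p = 0.0157). Gstm1 lost its call without replicate 1 or 2 (adjusted p = 0.0987 and 0.111). Also called lower were 7 of 9 Ces carboxylesterase genes (median -1.32, adjusted p = 0.00382) and 6 of 7 Fabp genes (median -2.58, adjusted p = 0.00111). Of 7 Csf genes, which encode colony stimulating factors and their receptors, 5 were called higher (median 2.17, adjusted p = 0.00467), as were 5 of 7 Gimap genes of lymphocytes (median 1.51, adjusted p = 0.0303). Medians of these 5 families kept their sign under the 6 scalings, but that of Gstm shrank to -0.46 with median centring and -1.22 with centring on the tested genes. Cross-hybridisation between close family members was not tested. Spike-in controls had intercepts of -0.15, -0.94 and -0.60 log2 units on replicates 1, 2 and 3.

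The gastric gland cell lists lay far below 0. Dilution of the whole epithelium by other tissue was tested against the epithelial junction and keratin list. The parietal median lay 3.47 log2 units lower (difference -3.47, 95% interval -4.41 to -1.77), which argues against dilution alone for that list. Differences were -3.05 (95% interval -3.86 to -1.93) for the mucous list and -2.19 (-3.32 to -1.28) for the endocrine list. For the chief cell list the difference was -3.29 with an interval of -7.04 to -0.09. The rule set beforehand asked for an interval wholly below -1, so dilution of the chief cell list could not be decided. Array scaling was tested as well, and the parietal median stayed at -2.74 or lower over the scalings tried, which argues against scaling for the parietal list. Of these, Aquantile changed no ratio and spike-in centring only shifts Agilent's processed ratios, so they are not independent checks. A loss of differentiated gland cells or of their gene expression in the tumours may account for the pattern as a hypothesis, and which of these applies was not tested.

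The stromal lists were all above 0 in median against a pool from which stroma had been removed. One common change in the share of stromal tissue was taken to raise them alike. The smooth muscle median minus the fibroblast and matrix median was -1.29 (95% interval -2.03 to -0.18, over genes and not over tumours). On replicates 1, 2 and 3 the smooth muscle medians were 0.49, 1.77 and 0.71, and the fibroblast and matrix medians 2.98, 2.51 and 1.47. The gap had the same sign on each array and was largest on replicate 1. Under that premise it argues against a common change as the whole cause. Removal of stroma that took different cell types unequally from the normal mucosae may remain an explanation, as may a fibroblast-rich tumour stroma, and neither was tested.

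Pancreatic acinar genes such as Amy2a5 and Clps were among those lowest in the tumours. If the pool held pancreatic tissue, islet genes would be seen in green and lower in the tumours. Of Ins1, Ins2, Iapp, Gcg and Ppy, 2 (Ins2 and Gcg) were well above background in green on all arrays with a ratio below 0. Gcg, not well above background in red on any array, was at least 2.99-fold lower (adjusted p = 0.00104 over all probes), and Ins2 at -0.12 ± 0.10 did not pass the test (adjusted p = 0.249), so pancreatic tissue in the pool could not be decided by islet genes. Of 16 genes of the acinar list with a probe, fixed before the data were seen, 5 were not well above background in green on any array, among them Cpa1, Cela2a and Cela3b. Of these 5, 2 were well above background in red on all arrays. Ctrb1 and Pnlip had mean log2 green signals of 6.82 and 6.94, against 19.33 for Clps and 16.36 for Amy2a5, but levels of different probes do not compare amounts. Cpa1 and Cela2a were well above background in neither channel on any array, so their probes were not shown to detect transcript here. In green, Sycn (13.27), Pnliprp1 (12.82), Cel (10.35) and Prss2 (10.05) were bright as well. Acinar tissue would bring all its abundant transcripts, but dim signals from probes of unknown affinity do not show that these were absent. Whether the pool held whole acinar tissue could therefore not be decided by these levels either. Expression of a part of the acinar programme by normal gastric gland cells may be a candidate explanation, and it was not tested.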
